A study of Homo sapiens with 9 samples.

How the data were processed

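Total RNA of LF1 human lung fibroblasts was measured by stranded sequencing after depletion of ribosomal RNA, with 3 proliferating, 3 quiescent and 3 senescent libraries. Per the labels' protocols, cells were grown in 15% serum and 2.5% oxygen, with quiescent cells held 1 to 2 days without serum after reaching confluence. RNA of proliferating and senescent cells was extracted with TRIzol and sequenced over 2 lanes, while quiescent cells were sent as pellets and sequenced on 1 lane. Extraction and lane are therefore confounded with quiescence. Groups were taken from the labels, and all 9 libraries were used.

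The gene counts are those the authors deposited, as whole numbers with no scaling. Per the submitters' processing notes STAR, HTSeq, edgeR and the hg38 genome were used, with no versions and no settings given. Whether reads were counted by strand is not stated, so genes that overlap others or lie antisense to them are uncertain. The count table holds 59531 rows: 58780 Ensembl genes, which are those of GENCODE 29, 649 numeric identifiers that no annotation at hand explains, 97 spike-in sequences of which 0 had a count, and 5 tallies of reads given to no gene. Tallies and spike-in sequences stayed out of library sizes and tests. Reads matching no gene made up 6.00% ± 1.47 of all reads in proliferating, 5.23% ± 0.807 in quiescent and 7.61% ± 0.378 in senescent libraries, and reads with several alignments 21.0% ± 0.694, 4.66% ± 0.698 and 5.89% ± 1.58. Every deposited count of the quiescent libraries is even, for a reason that no label gives, and the counts were used as deposited, with their division by 2 as an alternative. The authors deposited log2 fold changes and log2 mean CPM for senescent and for quiescent against proliferating cells, per the file headers. The score in those tables is the F statistic of the authors' test, per the file headers. The p-value and FDR columns come from the same test by the authors, and those tables hold every row of the count table, tallies included. They were compared with the results and used for nothing else.

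Depth over genes was 75.4 ± 5.87 M counts per proliferating, 266 ± 14.1 M per quiescent and 47.7 ± 1.46 M per senescent library. A gene with 3 counts over the proliferating libraries stands at 0.0131 CPM, and folds against a group with no count are given against that floor of 3 counts over the group. Floors and counting intervals cover counting error alone. No library was out of place in a check for mixed-up samples (0 of 9). No pair of columns held the same library: the counts of the closest pair in a state, senescent replicates 2 and 3, differed by a chi-square per degree of freedom of 6.76.

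Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes with low counts were removed with edgeR's filterByExpr, which left 19441 genes, 291 of them without a symbol, and libraries were scaled by TMM. A quasi-likelihood negative binomial model with 1 mean per state was fitted to the 9 libraries together (common dispersion 0.0354, prior degrees of freedom 8.58). The 3 comparisons were tested as contrasts of that model, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Standard errors come from the same model. The contrast of senescent against quiescent cells is also the test of the difference between the other 2 contrasts, since both share the proliferating libraries. Overlap of calls was set against that of independent lists and against 20 simulations of unchanged groups. Each simulation drew all 9 libraries around the mean of the proliferating libraries, and both comparisons shared the drawn proliferating libraries.

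For 26 gene lists, written from general knowledge before the data were examined, limma's camera test compared members with all other genes at a preset correlation of 0.01 between genes. It was repeated with a correlation estimated from the data, which with 9 libraries is a stricter test, and p-values were adjusted over the lists of each comparison. Lists with under 3 tested members were not tested. The number of members past the threshold is given with adjustment over all genes and, where it differs, over the list alone. Exon lengths, GC content, symbols and coordinates (hg38) come from GENCODE 29.

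Genes named in the text were chosen by a rule fixed before the data were examined. The rule takes the 6 largest rises and the 6 largest falls per comparison among called genes with a mean of at least 3 log2 CPM and groups that do not overlap, and the 3 called members of each list with the largest change, some of which are left out for length. It adds CDKN1A, CDKN2A, LMNB1, MKI67, HMGB2, IL6, CTCF, RAD21, DNMT1 and IFI27 in every comparison. Main tests, lists and most alternatives were likewise fixed before the data were examined.

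Alternatives were size factors as in DESeq2, upper-quartile scaling, scaling without mitochondrial and the 10 most abundant genes, no filter and a filter of 1 CPM in 3 libraries, the DESeq2 Wald test, limma-voom, fits of the 2 compared states alone, the replicate number as a block, a threshold of 0.01, a test against a log2 fold change of 1, and each library left out in turn. Another 3 were chosen after seeing the data: quiescent counts divided by 2, a smooth trend over exon length and GC content removed from each library (splines with 5 degrees of freedom), and protein-coding genes alone. With DESeq2 and with the trend removed, lists were tested by camera's preranked form on each gene's test statistic. The form of the list test thus changed together with those settings.

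The procedure was tested on simulated data with 200 changed genes drawn from the real libraries' means. With edgeR it recovered 98.5% of 4-fold, 71.6% of 2-fold and 10.4% of 1.5-fold changes for senescent against proliferating cells (17762 genes, 2 false calls). The figures were 100%, 76.1% and 8.96% for quiescent against proliferating (17779 genes, 13 false calls) and 100%, 79.1% and 19.4% for senescent against quiescent cells (17157 genes, 9 false calls). With a simulated trend over gene length, 6014 calls fell to 70 when the trend was removed (18086 genes). In these simulations a change of 1.5-fold was thus mostly missed. Far more genes were called in the real data, where the adjustment is less strict, so these shares may not carry over. Retrotransposon families, DNA methylation and chromatin contacts cannot be measured from these gene counts.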

Results

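Total RNA was sequenced from LF1 cells, a human lung fibroblast line that stops dividing after a limited number of passages, in 3 states with 3 libraries each. Proliferating cells were taken at 60 to 80% confluence, quiescent cells after reaching 100% confluence and 1 to 2 days without serum, and senescent cells after dividing to exhaustion and 3 to 4 further months in culture. The series sets these states side by side to find what characterises senescence as opposed to arrest that can be undone, with chromatin looping, loss of DNA methylation and retrotransposon activity as its themes. Gene counts summed to 68.7 to 79.6 M per proliferating library, 252 to 280 M per quiescent library and 46.5 to 49.3 M per senescent library. Every value of the quiescent libraries was even, where 51.2 to 55.9% of the non-zero values of the other libraries were odd, as if each quiescent read had been counted 2 times. The labels do not say that the 3 libraries of a state came from separate cultures, and p-values then measure only the spread between these libraries, which may be technical. Levels are TMM-scaled CPM, as mean ± SD over 3 libraries, and changes are log2 fold changes ± SE.

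The make-up of the libraries differed by state. Genes annotated as misc_RNA, mostly the signal recognition particle RNA gene RN7SL2, took 15.5% ± 2.12 of the counts in proliferating libraries, 1.49% ± 0.664 in quiescent and 0.521% ± 0.232 in senescent ones. Small nucleolar RNAs took 3.09% ± 0.120, 0.109% ± 0.0371 and 0.213% ± 0.0913. The 13 mitochondrially encoded messenger RNAs went the other way, with 0.182% ± 0.0195 in proliferating, 2.24% ± 0.604 in quiescent and 3.38% ± 0.919 in senescent libraries. Reads that matched more than 1 gene made up 20.7% ± 1.54, 8.48% ± 1.10 and 7.04% ± 1.38 of all reads. In both arrested states, shorter genes were lower against proliferating cells and longer genes higher. The Spearman correlation of fold change with exon length, across 19150 genes that are not independent replicates, was 0.26 for senescent, 0.33 for quiescent and -0.13 for senescent against quiescent cells.

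**Figure D1:**
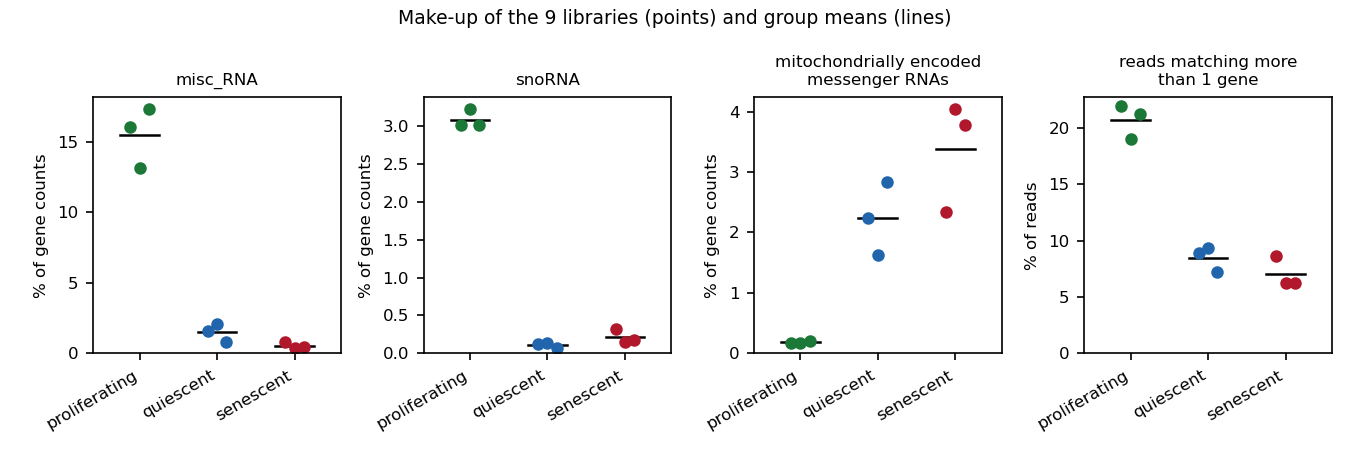
Share of gene counts taken by misc_RNA genes, small nucleolar RNAs and mitochondrially encoded messenger RNAs, and share of reads that matched more than 1 gene, in % (vertical axes), for the 9 libraries (points) by state, with the group mean (line). The 3 proliferating libraries stand apart from the other 6 in each panel, with misc_RNA at 13.2 to 17.3%.

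**Figure D2:**
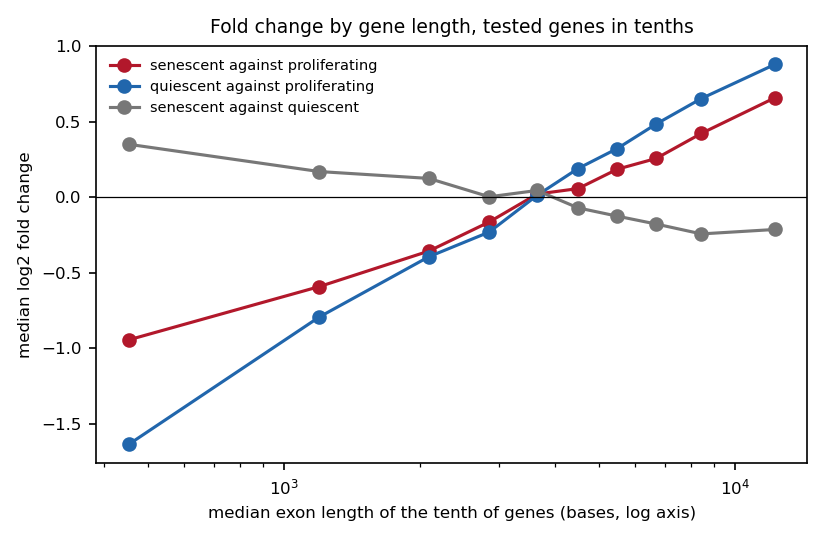
Median log2 fold change (vertical axis) of tested genes in 10 classes by exon length (horizontal log axis, median bases of each class), for the 3 comparisons (coloured lines). Against proliferating cells the median runs from -0.95 to 0.66 in senescent and from -1.64 to 0.88 in quiescent cells.

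The comparison of senescent with proliferating cells asked which genes change with replicative senescence. Senescent cells had less of the transcripts of the cell cycle, of DNA replication and of the replication-dependent histones, and more RNA of extracellular matrix genes and of FOXO and quiescence genes. CDKN2A, which encodes the inhibitor p16 and ARF (ENSG00000147889.17, a protein-coding gene at chromosome 9, 21967753 to 21995301, hg38), rose from 1.96 ± 0.201 to 51.1 ± 3.66 CPM, 26.2-fold. CDKN1A, the p53 target p21 (ENSG00000124762.13, chromosome 6, 36676460 to 36687339), rose 3.88-fold from 291 ± 36.9 to 1128 ± 171 CPM. LMNB1, lamin B1 of the nuclear lamina (ENSG00000113368.11, chromosome 5, 126776623 to 126837020), was 14.2-fold lower at 7.43 ± 1.02 CPM against 106 ± 14.3, and the chromatin protein gene HMGB2 was 25.3-fold lower.

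The largest changes named here and in the later comparisons are those among called genes with a mean of at least 3 log2 CPM and groups apart. The largest rises were those of GJA5, a gap junction protein gene (chromosome 1, 147756199 to 147773362), and CADM3, a cell adhesion molecule gene (chromosome 1, 159171609 to 159203313). Both had no count in proliferating libraries and stood at 69.3 ± 1.56 and 58.5 ± 1.37 CPM in senescent ones, at least 5286-fold and at least 4459-fold higher against a floor of 3 counts over the group. TMEM178B followed (10.09 ± 0.31), then the keratin gene KRT14 at 178 ± 27.0 against 0.184 ± 0.248 CPM, the potassium channel gene KCNN3 at 33.3 ± 5.44 against 0.0514 ± 0.0692, and the matrix gene MXRA5 at 610 ± 48.4 against 1.38 ± 0.521. Of the 6 largest falls, 5 were histone genes, led by HIST1H2AJ with 0.251 ± 0.117 against 674 ± 145 CPM, and HIST1H2BI, HIST1H2BB, HIST1H4L and HIST1H2AH had changes of -8.92, -8.71, -8.45 and -8.44. The other was SCARNA22, a small Cajal body RNA, at 0.0461 ± 0.0407 against 67.4 ± 2.68 CPM. Histone and small RNA genes have near-identical copies, so the count of any one copy is uncertain.

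All 30 mitosis genes fell, with a median of -3.74, among them BIRC5 (-5.08 ± 0.17) and CDK1 (-4.62 ± 0.19). MKI67, the proliferation marker Ki-67, was 3.52-fold lower, at 61.8 ± 10.7 CPM. All 34 genes of DNA replication fell as well (median -2.80), with CDC45 at -5.29 ± 0.18 and MCM7 at -4.46 ± 0.18. So did all 8 condensin genes (median -2.77), with NCAPG at -3.72 ± 0.20 and SMC4 at -3.36 ± 0.22. The 51 histone genes tested all fell, with a median of -6.65, or -6.63 with 1 gene at 0 set to its bound; their median exon length is 438 bases, in the range where all genes leaned to proliferating cells. Ribosome biogenesis had 23 of 25 genes lower and 1 higher, such as FBL, the snoRNA-guided methyltransferase fibrillarin (-3.08 ± 0.16), and BYSL (-2.97 ± 0.18). Against all other genes, limma's camera test gave adjusted p of 5.56e-29 for mitosis, 2.83e-26 for replication, 6.53e-79 for histones, 6.43e-07 for condensin and 5.48e-07 for ribosome biogenesis. These 5 calls held with an estimated correlation, at adjusted p of 0.0322, 0.0290, 0.0427, 0.0322 and 0.0322.

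Extracellular matrix genes rose in 28 of 31 cases and fell in 2 (median 2.81; camera adjusted p 2.54e-16, and adjusted p = 0.0322 with an estimated correlation). COL1A1, the major chain of type I collagen, reached 47446 ± 10006 CPM against 1441 ± 839, and MFAP5, a microfibril protein gene, 419 ± 74.9 against 3.59 ± 0.748. FOXO and quiescence genes rose in 17 of 20 cases and fell in 2 (adjusted p 3.02e-06, and adjusted p = 0.0290 with an estimated correlation), with the stress-response gene SESN3 at 6.19 ± 0.38 and FOXO1 at 3.69 ± 0.32. Lysosome genes rose in 19 of 28 cases and fell in 5 (adjusted p 0.000332, but adjusted p = 0.146 with an estimated correlation), with the proteases TPP1 at 4.24 ± 0.22 and CTSD at 3.56 ± 0.21. Among 24 p53 targets 14 rose and 6 fell (adjusted p 0.00297, but adjusted p = 0.132 with an estimated correlation), with the antiproliferative gene BTG2 at 3.79 ± 0.18 and ZMAT3 at 3.36 ± 0.16. Of the 13 mitochondrially encoded messenger RNAs 12 rose and 1 fell (adjusted p 4.23e-12, but adjusted p = 0.107 with an estimated correlation). MT-ND4 and MT-ND5, subunits of respiratory complex I, rose by 6.40 ± 0.33 and 6.38 ± 0.34, and the one that fell was MT-ND6 (-1.82), named here after its values were seen.

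Secreted senescence factors split, with 22 of 41 higher and 10 lower (median 0.71; adjusted p 0.00114, but adjusted p = 0.346 with an estimated correlation). The protease inhibitor gene SERPINE2 rose from 34.4 ± 2.53 to 2753 ± 262 CPM, IGFBP5 from 240 ± 59.5 to 11688 ± 235, IL1A from 0.178 ± 0.118 to 8.86 ± 1.82, and the cytokine gene IL6 from 5.17 ± 0.834 to 43.5 ± 4.03. Interferon-stimulated genes rose in 20 of 38 cases and fell in 5. That list missed the threshold at adjusted p 0.0612, with values from 0.00376 to 0.123 over other settings, and passed it without proliferating replicate 2 (0.0367), quiescent replicate 1 (0.0479), senescent replicate 1 (0.0357) or senescent replicate 2 (0.0238). Those values are camera's, and limma's fry test gave the list an adjusted p of 0.000979. OAS2, an antiviral enzyme gene, was at 1.13 ± 0.547 CPM against 2 counts in all 3 proliferating libraries, while IFI27 stood at 0.558 ± 0.154 against 0.651 ± 0.0957 CPM (adjusted p 0.632). Genes of cytosolic nucleic acid sensing and retrotransposon restriction went both ways, 10 higher and 9 lower of 24 (adjusted p 0.662). The cytidine deaminase gene APOBEC3C rose by 4.34 ± 0.22 and TMEM173, the adaptor STING, by 2.73 ± 0.17, while the DNA sensor gene CGAS was lower (-2.62 ± 0.20).

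Genes of chromosome folding were mostly lower. Of 18 genes of cohesin, its regulators and CTCF, 12 fell and 1 rose (median -0.64; adjusted p 0.0171, but adjusted p = 0.468 with an estimated correlation). The cohesin core gene SMC3 was 5.16-fold lower at 10.8 ± 2.28 CPM against 55.9 ± 14.1, RAD21 was 1.72-fold lower, and CDCA5, which keeps cohesin on sister chromatids, fell by 3.65 on the log2 scale. CTCF, the boundary protein gene, stood at 34.7 ± 1.48 against 39.6 ± 4.71 CPM (-0.19 ± 0.14, adjusted p 0.238), but was called lower with the trend over gene length and GC content removed (-0.70, adjusted p 8.84e-06) and among protein-coding genes alone (-0.34, adjusted p 0.0339). Nuclear lamina and heterochromatin genes fell in 11 of 20 cases and rose in 2 (adjusted p 0.00295, and adjusted p = 0.0440 with an estimated correlation), with the lamin B receptor gene LBR at -3.77 ± 0.18 and TMPO at -3.03 ± 0.17. The DNA methylation machinery had 6 of 13 genes higher and 6 lower (adjusted p 0.839), with a median of 0.26 and a mean of -0.17. UHRF1 and HELLS, both needed to keep methylation through replication, fell by 2.65 and 2.54 on the log2 scale, DNMT3B by 2.18 and DNMT1 by 0.54.

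The remaining lists were not called in this comparison. Senescence markers of mixed direction had 6 of 19 higher and 11 lower, CDKN2B among the former at 5.17 ± 0.21. Contractile genes had 7 of 16 higher and 6 lower (median 0.18, mean -0.21), with MYL9 at 2.77 ± 0.20 and DES at -5.15 ± 0.27, serum-response genes 12 and 12 of 27, with DUSP4 at 5.21 ± 0.29 and ODC1 at -2.85 ± 0.18, and cholesterol synthesis 11 and 10 of 24, with FDPS at -2.30 ± 0.18. Of 10 nuclear-retained RNAs 5 were higher, such as MEG3 (2.12 ± 0.27), and 1 lower, GAS5 (-3.11 ± 0.20). Among markers of other cell types, 3 of 11 epithelial genes were higher and 5 lower, with KRT14 up and the tight junction gene CLDN4 at -5.12 ± 0.24. Endothelial markers had 4 of 7 higher and 1 lower, with VWF at 2.52 ± 0.460 CPM against 0.153 ± 0.0887. Immune markers had 1 of 5 higher, CD14 at 2.65 ± 0.780 against 0.115 ± 0.0747 CPM, and pericyte and smooth muscle markers 4 of 9 higher, with NOTCH3 at 3.96 ± 0.33, and 5 lower. None of the 30 germline and cancer-testis genes had enough counts to be tested in any comparison. Camera's adjusted p for these lists lay between 0.148 and 0.887. Adjusted over the list alone, 11 genes of nucleic acid sensing and 15 p53 targets were higher, and the counts of the other lists stayed as given.

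In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 13325 of 19441 genes differed between senescent and proliferating cells, 6651 higher and 6674 lower, of which 4913 and 4910 by at least 2-fold. With the trend over length and GC content removed, 8538 were higher and 5866 lower. The 3 libraries of either state lay wholly above or below the other in 70.6% of tested genes, where chance gives 10%. A test against a 2-fold change left 7495 calls.

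**Figure D3:**
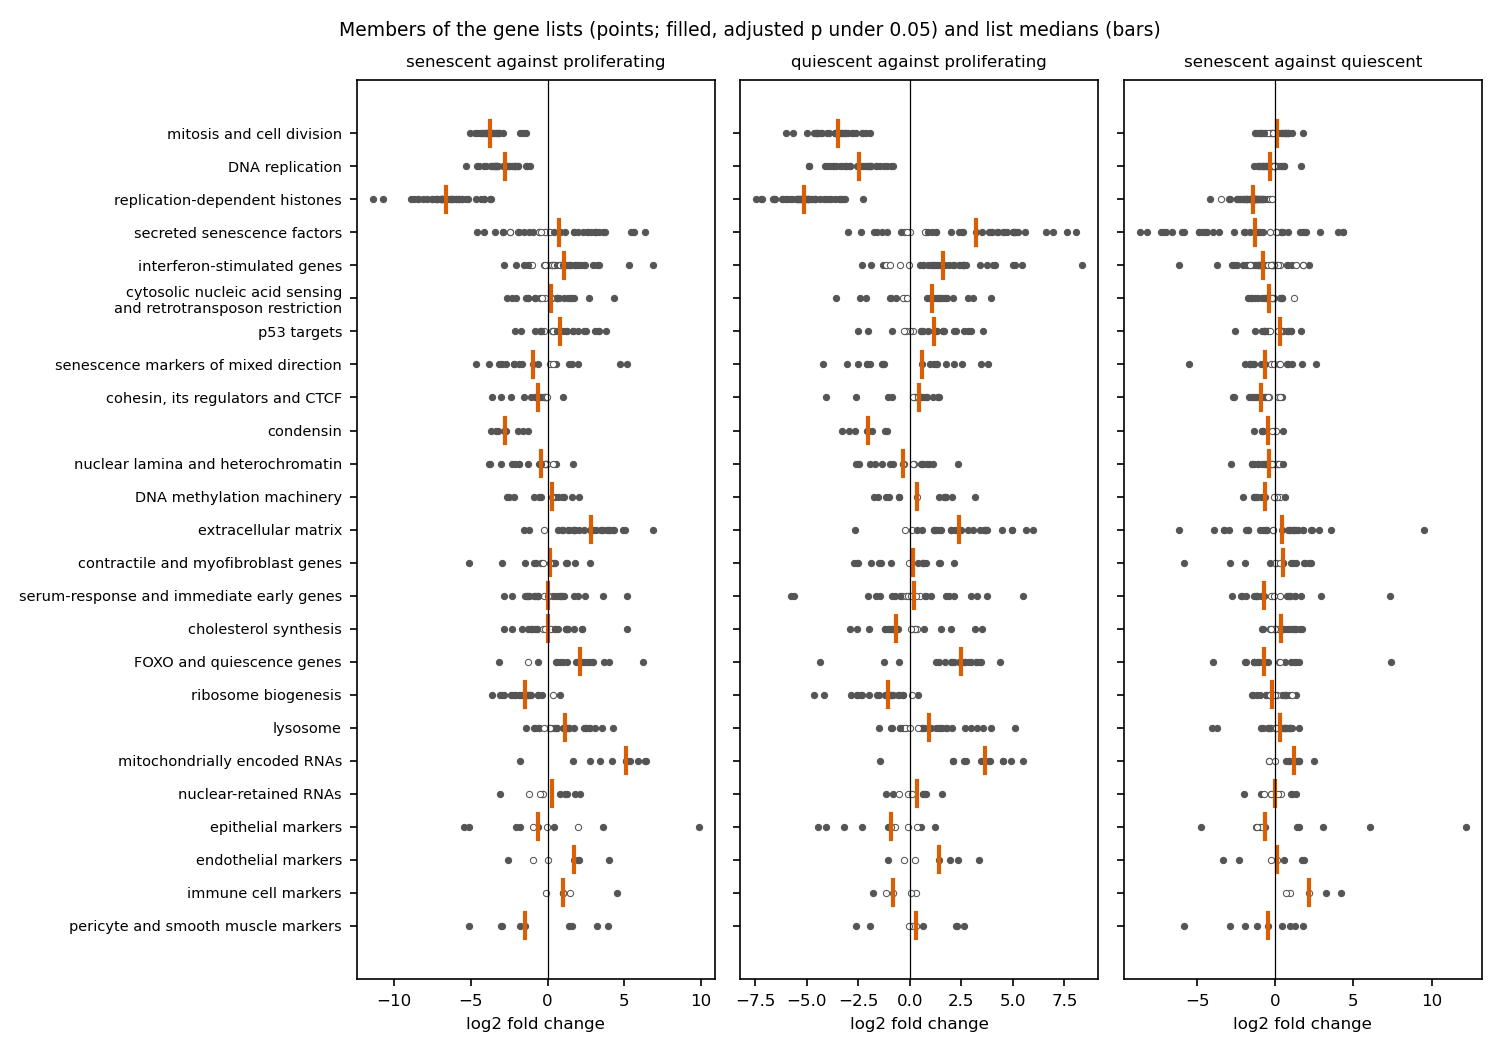
Log2 fold changes (horizontal axes) of the members of 25 gene lists (rows) in the 3 comparisons (panels, each with its own scale). Points are genes, filled where adjusted p was under 0.05, and bars mark the list medians; histones lie lowest against proliferating cells, with medians of -6.65 and -5.15.

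The comparison of quiescent with proliferating cells asked what arrest by confluence and serum withdrawal does. Cell cycle, replication and histone transcripts fell here too, and matrix genes and FOXO and quiescence genes rose. CXCL1, a neutrophil-attracting chemokine gene (ENSG00000163739.4, chromosome 4, 73869393 to 73871242), rose 200-fold, from 0.844 ± 0.673 to 166 ± 15.6 CPM, and CXCL10, an interferon-induced chemokine gene, from 0.0281 ± 0.0488 to 10.3 ± 1.80 CPM. Among called genes with a mean of at least 3 log2 CPM and groups apart, the largest rise was that of PPL, periplakin (chromosome 16, 4882507 to 4960741). It stood at 27.4 ± 2.38 against 0.0438 ± 0.0300 CPM. It was followed by the growth factor gene IGF2 (ENSG00000167244.19, chromosome 11, 2129112 to 2149603) at 105 ± 9.05 against 0.305 ± 0.109, WISP1 at 236 ± 5.54 against 0.811 ± 0.335, MTUS1, CXCL6 and TNFSF15, with changes of 8.12, 8.07 and 7.77. The 6 largest falls were those of short noncoding RNAs, RNY4, SCARNA22, SNORD15B, RNU5B-1, RN7SL471P and RN7SKP71, from -11.93 to -7.48. They belong to the classes that took more of the proliferating libraries' counts, and most have near-identical copies.

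All 30 mitosis genes, 34 replication genes, 51 histone genes and 8 condensin genes fell, with medians of -3.47, -2.45, -5.15 and -2.05. PTTG1, securin, stood at -6.03, BIRC5 at -5.68, GINS2 at -4.91, HIST1H2BB at -7.44 and NCAPH at -3.29, and MKI67 was 3.78-fold lower. Ribosome biogenesis had 23 of 25 genes lower and 1 higher, with RRP9 at -4.16 ± 0.22 and NOP56 at -2.83 ± 0.16. Camera's adjusted p was 3.68e-28 for mitosis and 8.77e-21 for replication, both of which held with an estimated correlation (0.0445 and 0.0436). It was 1.45e-53 for histones, 3.04e-05 for condensin and 1.53e-05 for ribosome biogenesis, but adjusted p = 0.0666, 0.0563 and 0.0607 with an estimated correlation.

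Matrix genes rose in 28 of 31 cases and fell in 1 (median 2.39; adjusted p 2.36e-13, and adjusted p = 0.0445 with an estimated correlation), with MFAP4 at 403 ± 15.9 against 6.31 ± 1.51 CPM and periostin, POSTN, at 512 ± 40.4 against 10.4 ± 1.57. FOXO and quiescence genes rose in 17 of 20 cases and fell in 3 (adjusted p 1.34e-07, and adjusted p = 0.0240 with an estimated correlation). YPEL3 and TXNIP rose by 4.39 ± 0.19 and 3.43 ± 0.20, and GADD45B was lower (-4.33 ± 0.16). Lysosome genes rose in 18 of 28 cases and fell in 6 (adjusted p 0.00219, but adjusted p = 0.219 with an estimated correlation), with the cathepsin gene CTSS at 5.10 ± 0.49. Of 24 p53 targets 16 rose and 3 fell (adjusted p 0.00403, but adjusted p = 0.161 with an estimated correlation), with TP53INP1 at 3.53 ± 0.18, BTG2 at 2.80 ± 0.17 and CDKN1A at 1.15 ± 0.17. The mitochondrially encoded messenger RNAs again had 12 higher and 1 lower (adjusted p 4.31e-08, but adjusted p = 0.187 with an estimated correlation), with MT-ND5 at 5.51 ± 0.32.

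Secreted senescence factors rose in 30 of 41 cases and fell in 7 (median 3.20; adjusted p 5.03e-10, but adjusted p = 0.108 with an estimated correlation), IL6 among the former at 31.3 ± 2.43 CPM. Interferon-stimulated genes rose in 31 of 38 cases and fell in 3 (median 1.61; adjusted p 3.87e-05, but adjusted p = 0.187 with an estimated correlation), and IFI27 was among those that fell, with 0.267 ± 0.102 against 0.651 ± 0.0957 CPM. Genes of nucleic acid sensing and restriction had 15 of 24 higher, such as APOBEC3C (3.94 ± 0.21) and APOBEC3F (3.09 ± 0.25), and 6 lower, such as RNASEH2A (-3.57 ± 0.47). Their adjusted p was 0.0531, with values from 0.00335 to 0.184 over other settings, and it fell under 0.05 in 7 of the 9 fits without 1 library, down to 0.0288 without proliferating replicate 3.

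Cohesin genes did not fall together here: 9 of 18 were higher and 4 lower (adjusted p 0.856). The loader gene MAU2 was 2.65-fold higher and CDCA5 fell by 4.08 on the log2 scale. CTCF was 1.47-fold higher (0.55 ± 0.14, adjusted p 0.00222), a call lost with the length and GC trend removed (0.07, adjusted p 0.530). RAD21 stood at 162 ± 21.1 against 140 ± 27.1 CPM (adjusted p 0.276, and 0.0433 without proliferating replicate 2). Lamina and heterochromatin genes had 7 of 20 higher and 8 lower, LMNB1 and LMNB2 among the latter at -2.49 ± 0.16 and -2.45 ± 0.16, and HMGB2 was 8.19-fold lower. The DNA methylation machinery had 6 of 13 higher and 6 lower. The demethylase genes TET1 and TET2 rose by 3.15 ± 0.23 and 2.03 ± 0.24, and DNMT1 was 1.45-fold lower.

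Senescence markers of mixed direction had 10 of 19 higher and 9 lower (median 0.61, mean -0.04), with CDKN1C, the inhibitor p57, at 3.79 ± 0.28, CDKN2A at 2.13 ± 0.19 and E2F1 at -4.22 ± 0.20. Contractile genes had 8 of 16 higher and 7 lower (median 0.17, mean -0.34). Smooth muscle actin, ACTA2, fell from 886 ± 70.9 to 136 ± 12.4 CPM and TAGLN by 2.58 on the log2 scale. Serum-response genes had 10 of 27 higher and 8 lower, with ODC1 at -5.75 ± 0.20 and ANKRD1 at -5.62 ± 0.24, and cholesterol synthesis 5 of 24 higher and 14 lower, with EBP at -2.89 ± 0.17. Nuclear-retained RNAs had 3 of 10 higher, such as TUG1 (1.55 ± 0.18), and 2 lower. Epithelial markers had 2 of 11 higher and 5 lower, with CLDN4 at -4.45 ± 0.22 and KRT7 at -3.19 ± 0.17. Endothelial markers had 4 of 7 higher and 1 lower, with CDH5 at 0.315 ± 0.0189 against 0.0291 ± 0.0256 CPM, and pericyte markers 4 of 9 higher and 2 lower, with PDGFRB at 2.61 ± 0.17 and KCNJ8 at -2.61 ± 0.18. Of 5 immune markers 1 was lower, FCER1G at 0.0608 ± 0.0169 against 0.210 ± 0.155 CPM, and this call (adjusted p 0.0486) was lost in most fits without 1 library, such as 0.240 without proliferating replicate 3, and with the replicate block (0.109), limma-voom (0.0945) and quiescent values divided by 2 (0.0516). Adjusted p for these lists, lamina and methylation lay between 0.192 and 0.856. Adjusted over the list alone, 31 secreted factors, 17 p53 targets and 7 methylation genes were higher, 4 interferon-stimulated genes and 0 immune markers were lower, and the other counts stayed as given.

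The quasi-likelihood test called 14113 genes, 7332 higher and 6781 lower, of which 5287 and 5157 by at least 2-fold, and the groups lay apart in 74.4% of tested genes (10% by chance). With the trend over gene length and GC content removed the split was 9253 higher and 5634 lower, with upper-quartile scaling 6736 and 7362, and with DESeq2 7481 and 7858. Quiescent cells were sent for sequencing as pellets and run on a lane of their own, so extraction and lane cannot be told apart from quiescence in this comparison or the next.

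The comparison of senescent with quiescent cells asked what sets lasting arrest apart from arrest that can be undone, and it is also the test of the difference between the effects above. Quiescent cells had been at 100% confluence and without serum, and senescent cells in 15% serum for 3 to 4 further months. Serum and time in culture therefore cannot be told apart from the kind of arrest here, and the confluence of senescent cells is not given. Senescent cells had more CDKN2A (5.98-fold, 51.1 ± 3.66 against 8.55 ± 2.01 CPM), less LMNB1 (2.53-fold) and HMGB2 (3.09-fold), and less of the chemokine genes CXCL1, CXCL6 and CXCL5. CXCL1 stood at 0.565 ± 0.217 against 166 ± 15.6 CPM, CXCL6 at 0.0767 ± 0.0546 against 31.1 ± 2.13 and CXCL5 at 0.0912 ± 0.0699 against 14.7 ± 0.939. Cohesin genes were lower in 13 of 18 cases (camera adjusted p 0.00239, but adjusted p = 0.441 with an estimated correlation). In this comparison no list had a lower adjusted p with an estimated correlation, so none passed that stricter test. SMC3 (chromosome 10, 110567691 to 110604636) stood at 10.8 ± 2.28 against 69.6 ± 4.79 CPM and STAG2 at 21.3 ± 4.86 against 134 ± 12.1. MKI67 (61.8 ± 10.7 against 57.4 ± 11.6 CPM, adjusted p 0.682) and DNMT1 (adjusted p 1.00) were not told apart.

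The largest rises were those of GJA5 at 69.3 ± 1.56 against 0.0119 ± 0.0151 CPM, KRT14 (ENSG00000186847.5, chromosome 17, 41582279 to 41586921) at 178 ± 27.0 against 0.0375 ± 0.0153, RNY4, CADM3, MFAP5 (ENSG00000197614.10, chromosome 12, 8637346 to 8662888) at 419 ± 74.9 against 0.562 ± 0.199, and UNC13A, a synaptic vesicle priming gene, at 29.8 ± 1.82 against 0.0467 ± 0.00477. The largest falls were IGF2 at 0.0616 ± 0.0676 against 105 ± 9.05 CPM, CXCL6, the scavenger receptor gene COLEC12 (-8.26 ± 0.26), CXCL1, TNFSF15 (-7.36 ± 0.50) and the ion channel gene TRPA1 (-7.35 ± 0.26).

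**Figure D4:**
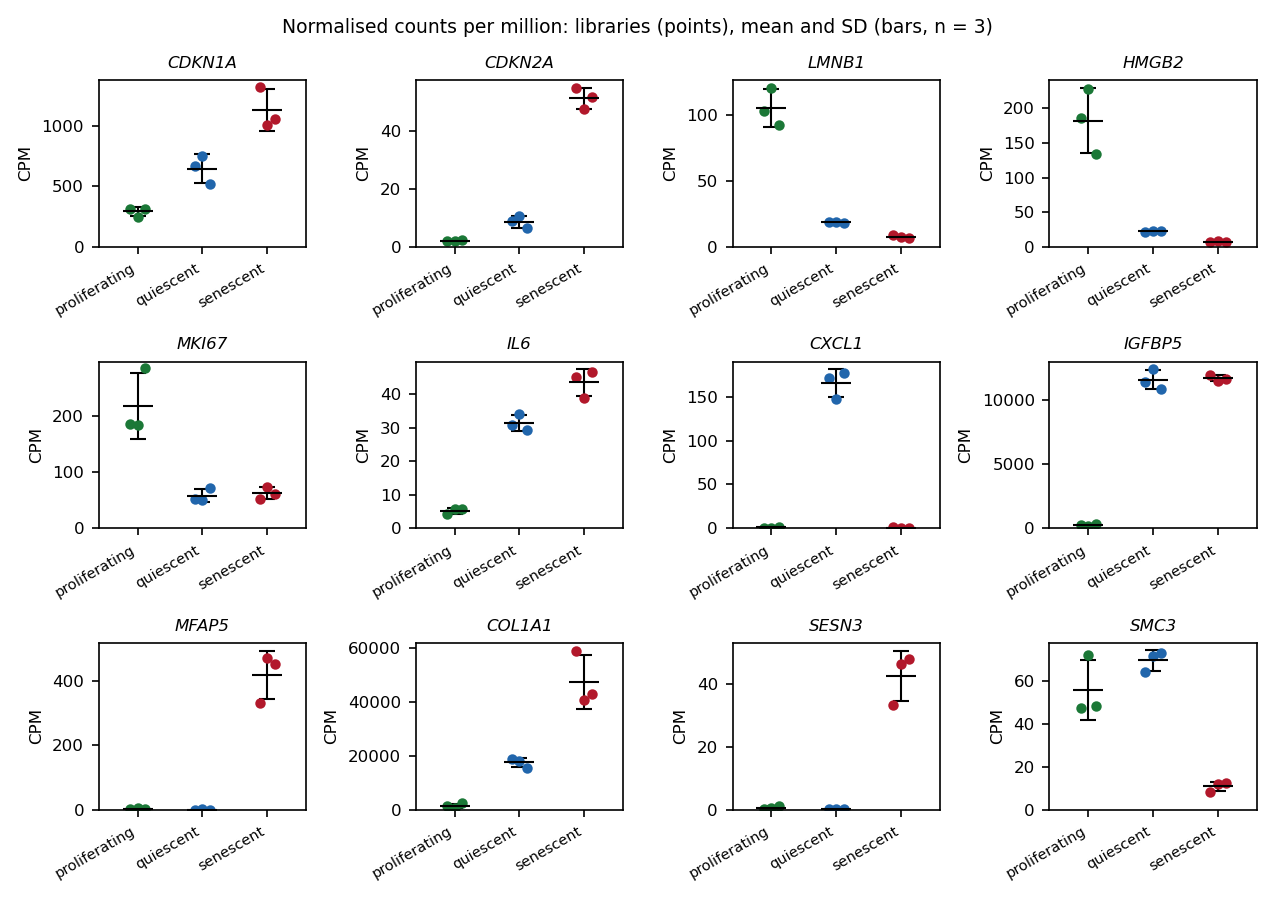
TMM-scaled CPM (vertical axes, from 0, each panel with its own scale) of 12 named genes in the 9 libraries (points) by state, with mean and SD (bars, n = 3). CXCL1 stands out in quiescent libraries (166 ± 15.6 CPM), MFAP5 and SESN3 in senescent ones, and SMC3 is lowest in senescent ones (10.8 ± 2.28 CPM).

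Secreted factors had 11 of 41 genes higher in senescent than in quiescent cells and 25 lower (median -1.30; adjusted p 0.000575, but adjusted p = 0.441 with an estimated correlation). IL6 was 1.39-fold higher (adjusted p 0.0169), a call lost with no filter on low counts (0.158) and without quiescent replicate 1 (0.0686), quiescent replicate 3 (0.0582), senescent replicate 1 (0.0540) or senescent replicate 3 (0.0968). Interferon-stimulated genes were higher in 5 of 38 cases and lower in 19 (adjusted p 0.00892, but adjusted p = 0.441 with an estimated correlation), with CXCL10 at -6.15 ± 0.49, IFITM1 at -3.73 ± 0.26 and the RNA sensor gene IFIH1 at -2.75 ± 0.35. IFI27 was 2.08-fold higher (adjusted p 0.0325), a call lost without quiescent replicates 1 (0.111) or 3 (0.112), senescent replicates 1 (0.140) or 2 (0.0911), with no filter on low counts (0.110) or with the length and GC trend removed (0.0925). Genes of nucleic acid sensing and restriction had 1 of 24 higher and 11 lower (adjusted p 0.104, with values from 4.77e-05 to 0.251 over other settings), among them the kinase gene TBK1 at -1.65 ± 0.22 and the silencing gene MPHOSPH8 at -1.58 ± 0.19.

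The cohesin list had 1 gene higher beside its 13 lower (median -0.91; adjusted p 0.00239, but adjusted p = 0.441 with an estimated correlation), with STAG1 at -1.66 ± 0.18, RAD21 at -0.99 ± 0.17 and CTCF at -0.74 ± 0.14. Lamina and heterochromatin genes had 10 of 20 lower, such as LBR (-2.82 ± 0.17) and CBX3 (-1.50 ± 0.20), and 1 higher. Their adjusted p was 0.0365, but adjusted p = 0.441 with an estimated correlation, and the call was lost with upper-quartile scaling (0.0531), a stricter filter on low counts (0.130) and protein-coding genes alone (0.126). Histones were lower in 48 of 51 cases (median -1.41, or -1.40 with 1 gene at its bound; adjusted p 5.28e-12, but adjusted p = 0.489 with an estimated correlation), with HIST1H2AJ at -4.20 ± 0.36. The mitochondrially encoded messenger RNAs were higher in 10 of 13 cases, MT-ATP8 by 2.51 ± 0.20 and MT-CO2 by 1.48 ± 0.18, and lower in 1. Their adjusted p was 0.0313, but adjusted p = 0.656 with an estimated correlation, and it rose to 0.198 with the length and GC trend removed, 0.0758 with the 2 groups fitted alone, 0.0670 with a stricter filter and 0.0619 without quiescent replicate 2.

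Camera called no other list, with adjusted p between 0.104 and 0.973. Limma's fry test passed some of them, such as nucleic acid sensing (adjusted p 0.000442), DNA methylation (0.000537) and mixed senescence markers (0.000369). It did not pass others, such as mitosis (0.527) and p53 targets (0.680). Mitosis genes had 12 of 30 higher and 8 lower, with PTTG1 at 1.77 ± 0.19 and CENPF at -1.29 ± 0.20, replication genes 4 of 34 higher and 14 lower, with MCM7 at -1.37 ± 0.16, condensin 1 of 8 higher and 4 lower, with SMC4 at -1.35 ± 0.20, and ribosome biogenesis 7 of 25 higher and 6 lower, with NPM1 at -1.42 ± 0.19. Among 24 p53 targets 9 were higher, CDKN1A by 0.81 ± 0.17, and 9 lower, PLK2 among them at -2.56 ± 0.16. Senescence markers of mixed direction had 5 of 19 higher and 10 lower, with CDKN1C at 0.412 ± 0.300 against 18.5 ± 0.910 CPM and CDKN1B, the inhibitor p27, at -1.91 ± 0.14. Methylation genes had 1 of 13 higher and 7 lower, with TET1 at -2.09 ± 0.22. Matrix genes divided into 16 higher and 13 lower of 31, with the basement membrane gene FBLN1 at 17.6 ± 1.81 against 1252 ± 37.3 CPM and COL12A1 at -3.89 ± 0.17. Contractile genes had 9 of 16 higher, ACTA2 by 2.30 ± 0.15, and 4 lower, DES by -5.82 ± 0.28, and serum-response genes 9 of 27 higher, ANKRD1 by 7.31 ± 0.26, and 14 lower. Cholesterol synthesis had 12 of 24 higher and 2 lower. FOXO genes had 6 of 20 higher, SESN3 by 7.43 ± 0.39, and 12 lower, such as PDK4 (-3.98 ± 0.70), and lysosome genes 12 of 28 higher and 6 lower, CTSK by -4.07 ± 0.21 (median 0.32, mean -0.01). Nuclear-retained RNAs had 3 of 10 higher, such as MEG3 (1.32 ± 0.26), and 2 lower, with a median of -0.05 and a camera direction upwards.

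Of the other cell types, epithelial markers had 5 of 11 higher, with KRT14 and CDH1 (0.819 ± 0.0667 against 0.0115 ± 0.0105 CPM), and 4 lower, so that the median was -0.66 and the mean 1.32. Endothelial markers had 3 of 7 higher and 2 lower (median 0.13, mean -0.24), immune markers 2 of 5 higher, with CD14 at 2.65 ± 0.780 against 0.143 ± 0.0206 CPM, and pericyte markers 4 of 9 higher and 5 lower, with ABCC9 at -1.95 ± 0.22. Adjusted over the list alone, 10 p53 targets were higher, 0 genes of nucleic acid sensing were higher, 14 cohesin genes and 5 epithelial markers were lower, and the other counts stayed as given. The quasi-likelihood test called 10780 genes, 5200 higher and 5580 lower, of which 3322 and 3189 by at least 2-fold, with the groups apart in 67.8% of tested genes (10% by chance). Which direction had more calls turned with the processing: 5931 were higher and 4785 lower with upper-quartile scaling, 5472 and 5250 with size factors as in DESeq2, 5859 and 5190 with DESeq2, and 4763 and 6479 with no filter.

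Senescent and quiescent cells shared much of their difference from proliferating cells. Of the calls against proliferating cells, 4901 were higher and 4884 lower in both states, where independent lists of these sizes would share 2508 and 2328. With the trend over length and GC content removed, 6545 were higher and 4012 lower in both. Of the shared calls, 2270 higher and 2713 lower genes did not differ between the arrested states at this threshold. Another 429 genes rose in senescent and fell in quiescent cells and 562 did the opposite. The fold changes of both comparisons had a Pearson correlation of 0.73 across genes and a covariance of 3.87. In 20 simulations that drew all 9 libraries around the mean of the proliferating ones, no call was shared, the correlation was 0.50 ± 0.01 (SD) and the covariance 0.0535. The observed covariance exceeded by 3.82 what noise in shared controls gave there. The simulations hold no difference in make-up between the states, such as that of short RNAs, which could move both comparisons alike. Part of the excess overlap may still come from the shared controls, since 3 libraries cannot be split into parts of at least 2 each.

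Genes that set senescent cells apart from both other states numbered 5336, 2794 higher and 2542 lower, of which 1627 and 1223 by at least 2-fold in both comparisons. KRT14, MFAP5, GJA5, CADM3, CDKN2A and CDKN1A were among the higher ones, and SMC3, LBR, LMNB1, HMGB2, RAD21 and GAS5 (54.7 ± 10.8 CPM against 472 ± 96.3 and 215 ± 24.2) among the lower ones. Counted the same way, 9785 genes set proliferating cells apart and 5989 quiescent cells. The authors' deposited tables call 13474 rows at an adjusted p under 0.05 for senescent against proliferating cells, 6864 higher and 6610 lower, and 15012 for quiescent against proliferating cells, 8006 higher and 7006 lower. Of the calls made here, the authors' tables make 93.6% and 93.2% in the same direction and none in the opposite one.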

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

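The tests of reads shared with KRT17, of gene length and GC content, of a factor per library as the source of the difference between gene classes, and of more mitochondria were chosen after the results were seen. The contrast between both arrested states gives the size of the difference for the genes below. It is no independent test of them, since they were picked from the same libraries by their calls against proliferating cells. They stand out because senescent and quiescent cells were called in opposite directions from proliferating cells. For KRT14 this rests on 1 library: it rose by 9.84 in senescent cells on the log2 scale, but its change of -2.34 in quiescent cells was -0.13 (adjusted p 0.864) without proliferating replicate 2, and its rise then 12.06; the difference between the arrested states was 12.18. The differences were 9.54 for MFAP5 (6.86 and -2.68), 9.29 for UNC13A (7.46 and -1.83), -10.73 for IGF2 (-2.31 and 8.42), -8.26 for COLEC12 (-4.14 and 4.13) and -7.35 for TRPA1 (-3.10 and 4.25). Without proliferating replicate 3 the quiescent change of UNC13A was -0.98 (adjusted p 0.0448), and without senescent replicate 1 the senescent change of IGF2 was -3.69. For cohesin, its regulators and CTCF the list median was -0.91 between the arrested states, with -0.64 in senescent and 0.46 in quiescent cells against proliferating cells. The quiescent change was not called (adjusted p 0.856), and with an estimated correlation the calls between the arrested states (adjusted p 0.441) and in senescent cells (0.468) were lost. Between the arrested states no list passed with an estimated correlation.

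KRT14 is a keratin of basal epithelial cells and stood at 178 ± 27.0 CPM in senescent libraries. Basal epithelial cells in the cultures would bring their other abundant transcripts. Of 18 other basal markers listed before that test, 10 stayed under 1 CPM, and their median was 0.0958 CPM; KRT5, the usual partner of KRT14, was at 0.0388 CPM, KRT16 at 8.52 and LAMB3 at 11.3, values looked up after the test. Some markers rose beside KRT14, from proliferating to senescent cells: DSP from 42.2 to 540 CPM, PERP from 37.4 to 129, KRT17 from 0.666 to 7.996, KRT16 from 0 to 8.52 and TRIM29 from 0.0185 to 1.13. Reads shared with KRT17 would keep the ratio of both genes, and the lowest KRT14 to KRT17 ratio of a senescent library exceeded the highest of a proliferating library 27.4 times. Both tests argue against these explanations. KRT14 may be expressed by senescent fibroblasts, with some other keratin and desmosome genes, which was not tested in other cultures. Whether reads of KRT14 added to the counts of KRT16 and KRT17 was not tested.

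Short and structured RNAs took more of the counts in proliferating libraries. With the trend over gene length and GC content removed, lists were tested by camera's preranked form. Adjusted p with and without the trend thus come from unlike tests, and the directions compare more directly. Gene length and GC content as the whole cause of the list calls are argued against, since 100% of the 25 list calls against proliferating cells stood in their direction with that trend removed. For the short RNAs themselves they stay open: with the trend removed the medians in senescent cells went from -2.53 to 0.24 for misc_RNA, -2.33 to 1.26 for snoRNA, -2.99 to 0.25 for snRNA and -2.52 to 0.61 for scaRNA, and those in quiescent cells from -3.59 to 0.25, -4.13 to 0.85, -4.12 to 0.72 and -4.20 to 0.01, but the trend was fitted on these short genes too. Proliferating libraries counted without strand would raise the change of genes overlapped on the opposite strand by at least 1. Without that cause the 2 medians were to differ by less than 0.25. The difference was -0.304 (bootstrap SE 0.265) and met neither rule. It lies on the side away from the rise that this explanation requires. Counting without strand would also add to the reads that match more than 1 gene. These took 20.7% in proliferating, 8.48% in quiescent and 7.04% in senescent libraries, so the explanation stays open. A few abundant genes setting the scale were to be tested by the share of higher calls with such genes left out of scaling (48.2% against 49.9%), which decides nothing, since scaling centres the changes near 0. A factor per library moves all genes alike, so it cannot set gene classes apart, and without the 10 most abundant genes the median change in senescent cells of 329 short RNA genes differed from that of protein-coding genes by -2.55 (bootstrap SE 0.191). That value restates the pattern and is no independent test; it leaves open how far scale moved all genes together. A yield of short RNAs that varies between library preparations cannot be told apart from state: in 2 of 3 groups, and not in all, the library with the most misc_RNA leaned most to short genes, and preparation may have differed between the states. A change of these RNAs with the state of the cells stays open, untested.

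Mitochondrially encoded messenger RNAs were lower in proliferating libraries. Gene length and GC content would have to raise them in senescent cells, where their median change was 5.14, and the fitted trend lowered each of the 13, by a median shift of -1.97 (-3.41 to -1.05). More mitochondria with all that they hold would raise nuclear-encoded subunits of oxidative phosphorylation, MT-ND6 and mitochondrial transfer RNAs. The subunits had a median of -1.81, or -1.22 with the trend over length and GC content removed. MT-ND6, chosen after its values were seen, fell as well (-1.82). The transfer RNAs had 3 of 14 higher and 9 lower, with a median of -1.30. That median turned to 2.65 with the trend removed, so the transfer RNAs decide nothing. A difference in preparation between the groups, or one that comes with arrest, could underlie this pattern, and neither was tested.

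For each comparison, the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split, 1 of the 10, called 13325 genes for senescent against proliferating, 14113 for quiescent against proliferating and 10780 for senescent against quiescent cells, and the highest other split called 0 in each. Of 100 splits of the 9 libraries into 3 groups, 3 set at least as many genes apart from both other groups as the 5336 of senescent cells, the real split included. The other 2 (7706 and 7730 genes) had the 3 proliferating libraries as the group set apart, so they show the structure of the states. The share of 3 in 100 is under 0.05, which argues against labels given to the libraries at random. Most splits that mix states set 0 genes apart, since unlike libraries in 1 group widen its spread. The test thus cannot tell the state of the cells from preparation or anything else that the libraries of a state share.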

How the results depend on the processing

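The 3 alternatives that divide quiescent values by 2, remove the trend over gene length and GC content, or keep protein-coding genes alone were chosen after the data were seen. Counts of called genes stayed within 1.5 times of those reported under all settings but 1. The test against a log2 fold change of 1 called 7495 genes for senescent against proliferating (3776 higher, 3719 lower), 8095 for quiescent against proliferating (4025, 4070) and 3777 for senescent against quiescent cells (1978, 1799), with 1645 set apart from both (1030, 615) and 4900 shared (2334, 2566), fewer because small changes no longer count. At an adjusted p under 0.01, 11444, 12292 and 8234 genes were called. Under the other settings, fits of the 2 compared states alone included, the counts ran from 10344 to 14404, 10414 to 15833 and 8484 to 12192. Without 1 library they ran from 12514 to 13829, 13438 to 14654 and 9341 to 11881, with 4526 to 5867 set apart and 9241 to 10146 shared. Upper-quartile scaling moved the median of all genes by -0.13 for quiescent against proliferating and 0.13 for senescent against quiescent cells, and removing the trend by 0.31 for senescent and 0.32 for quiescent against proliferating cells. With the trend removed 83.7%, 81.5% and 92.1% of calls were kept in the 3 comparisons and 267, 482 and 6 turned direction. With quiescent values divided by 2, 100%, 99.2% and 98.6% were kept.

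Each of the 75 gene list results was counted under each setting, and direction was checked only where the result was called as reported. Over settings other than a library left out, 867 of these counts kept their side of the threshold, 21 passed it anew and 6 lost it. With a library left out the numbers were 663, 11 and 1. For genes taken by the naming rule, some left out of the text, they were 2426, 2 and 7, with 1 reversal, and 1830, 1 and 14. In what follows each list has its median and camera's adjusted p, and the cause was not tested. For DESeq2 and the trend removed, that p comes from camera's preranked form. For senescent against proliferating cells, interferon-stimulated genes were called with no filter (1.15, 0.00376), DESeq2 (1.19, 0.0318), limma-voom (1.01, 0.0303) and the trend removed (1.08, 0.0132), and without 1 library ranged from 0.78 to 1.33 (0.0238 to 0.119). Senescence markers of mixed direction were called with no filter (-0.96, 0.0353). For quiescent against proliferating cells, nucleic acid sensing was called with no filter (1.21, 0.00335) and DESeq2 (1.07, 0.0121), and without 1 library ranged from 1.07 to 1.16 (0.0288 to 0.0630); lamina genes were called with the trend removed (-0.13, 0.0175).

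For senescent against quiescent cells, no filter also called replication (-0.45, 0.000229), nucleic acid sensing (-0.57, 4.77e-05), mixed senescence markers (-0.80, 0.0107), condensin (-0.62, 0.0280), DNA methylation (-0.77, 0.00157) and FOXO genes (-0.89, 0.0202). Nucleic acid sensing was also called with DESeq2 (-0.40, 0.0280) and limma-voom (-0.41, 0.0285), cholesterol synthesis with the trend removed (0.23, 0.0393) and epithelial markers with the 2 states alone (-0.66, 0.0175; as reported, camera ranked this list higher, with a mean of 1.32). Lamina genes lost their call with upper-quartile scaling (-0.29, 0.0531), the stricter filter (-0.34, 0.130) and protein-coding genes alone (-0.34, 0.126). Mitochondrially encoded RNAs lost theirs with the stricter filter (1.31, 0.0670), the trend removed (0.90, 0.198) and the 2 states alone (1.23, 0.0758), and without 1 library ranged from 1.03 to 1.43 (0.000711 to 0.0619, the highest without quiescent replicate 2). FCER1G, lower in quiescent cells (-1.76, edgeR adjusted p 0.0486), turned to 0.059 (0.949) with the trend removed, at levels under 1 CPM, and lost its call with the replicate block (-1.42, 0.109), limma-voom (-1.46, 0.0945) and quiescent values divided by 2 (-1.78, 0.0516).

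Replicate numbers did not pair the libraries: 5 of 9 correlations between libraries of the same number were over 0.1 (-0.55 to 0.61), and 1 of 9 libraries correlated best with its own number. Between libraries of other numbers they ran from -0.70 to 0.66, so libraries of different states shared deviations that the main model leaves out. Deviations of protein-coding genes also correlated with exon length, from -0.341 in quiescent replicate 2 to 0.323 in senescent replicate 2 (Spearman). The source of these deviations was not tested. With the replicate block 6639 genes were higher and 6603 lower for senescent against proliferating, 7325 and 6627 for quiescent against proliferating and 5028 and 5581 for senescent against quiescent cells. The replicate block also called interferon-stimulated genes in senescent against proliferating cells (0.96, 0.0466) and nucleic acid sensing in quiescent against proliferating (1.10, 0.0430) and senescent against quiescent cells (-0.43, 0.0429). Depth limits calls least in quiescent libraries. Changes of 1.5-fold were mostly missed in the simulations, which may not carry over to the real data. There, some changes smaller than 1.5-fold were called, such as those of IL6 between the arrested states and CTCF in quiescent against proliferating cells.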

Other observations

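The gene classes below were chosen after their values were seen. Ribosomal protein genes fell in senescent against proliferating cells in 77 of 78 cases and rose in 1 (median -2.29; limma's camera test, adjusted p 5.12e-33, but adjusted p = 0.124 with an estimated correlation). In quiescent cells 69 fell and 3 rose (median -1.47, estimated adjusted p 0.201), and in senescent against quiescent cells 66 were lower and 5 higher (median -1.09, estimated adjusted p 0.251). With the trend over length and GC content removed the 3 medians were -1.92, -0.88 and -1.21. Nuclear-encoded subunits of oxidative phosphorylation fell in 72 of 81 cases in senescent and 76 of 81 in quiescent cells, with medians of -1.81 and -1.95 (-1.22 and -1.11 with the trend removed), and rose in 3 and 1; with an estimated correlation adjusted p was 0.193 and 0.177. Genes named ZNF, most of which encode zinc finger repressors, were higher in 225 and lower in 86 of 447 cases in quiescent against proliferating cells. Their median was 0.46 (camera adjusted p 0.0259, but adjusted p = 0.541 with an estimated correlation). In senescent against quiescent cells 33 were higher and 249 lower, with a median of -0.58 (camera adjusted p 3.23e-06, but adjusted p = 0.251 with an estimated correlation). Against proliferating cells, senescent cells had 110 of them higher and 172 lower (camera adjusted p 0.259, and adjusted p = 0.729 with an estimated correlation).

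Processed pseudogenes, whose reads can come from their parent genes, were lower in 444 and higher in 62 of 736 cases in senescent against proliferating cells, with a median of -2.26, or -0.28 with the trend over length and GC content removed. In quiescent against proliferating cells 487 were lower and 89 higher, and the median of -2.16 turned to 0.17 with the trend removed.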
